A study of Mus musculus with 2 samples.

How the data were processed

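Total RNA was measured by RNA sequencing in the hearts of 2 female mice of the F1 strain labelled B6CASTF1/J, at 4 days of age. Per the labels, the libraries were stranded and ribosome-reduced, started from 300 ng of RNA, and carried ERCC spike-ins, synthetic RNAs added to the samples. The labels give the libraries separate biological replicate numbers but the same donor, so that they come from separate animals rests on those numbers alone. They were treated as biological replicates 1 and 2 of a single group. No contrast between groups is possible in this design. With 2 libraries the smallest two-sided permutation p is 0.5, so no p-value was computed.

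For each library the authors deposited a gene table and a pair of transcript tables on the mm10 genome with annotation M21, per the file headers and accompanying notes. The gene table holds estimated counts (expected counts that need not be whole) and TPM as deposited by the authors, together with posterior means and posterior standard deviations of the counts. Its columns have the layout of RSEM. The second transcript table has the column layout of kallisto, and also holds estimated counts and TPM deposited by the authors. The names and versions of the quantification programs are not given in the sources used here. The gene tables hold 55536 annotated genes, 26248 features identified by a number only, 96 spike-ins and phiX. All annotated genes matched GENCODE M21 by identifier, from which symbols, gene classes and coordinates (1-based) were taken. Values of the second quantification were summed per gene, and 86 annotated genes had none. Posterior SDs were used only to mark genes whose reads can be shared with near-identical copies or other genes.

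Expected counts totalled 36175363 in replicate 1 and 32509660 in replicate 2. A count of 0 allows up to 3 counts, which is 0.0829 CPM in replicate 1 and 0.0923 in replicate 2. Intervals and this limit cover counting error only, since reads without molecular identifiers are not independent molecules.

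The named lists (44), gene pairs (30) and isoform genes (25), the rules of comparison and most alternatives were fixed before the data were examined. The neutrophil, platelet and interferon lists, the tests of explanations and a few added alternatives were chosen after the results were seen. Of the list symbols, 4 were not found in the annotation. Named genes were the 10 with the highest mean TPM at an effective length of at least 200 nt, the members of detected pairs, up to 4 members per list by TPM with the members at 0 counts, the 10 largest ratios in each direction between the hearts, the sex-linked lists, and the isoform genes. Genes outside this rule are said to have been chosen after their values were seen.

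Levels are given as TPM with mean ± SD of the 2 libraries. For a pair, the log2 ratio of TPM was taken in each library. A pair was called when both libraries had the same sign and the smaller ratio exceeded the 95th percentile of the between-library difference over 10000 random gene pairs matched on expression decile. That spread does not cover differences in how well 2 genes can be measured. Between the hearts, expected counts were rounded to whole numbers, scaled by TMM (edgeR 4.0.16, R 4.3.3) and given a prior count of 0.5. A gene was called at a ratio of at least 2-fold, a mean TPM of at least 1, a summed count of at least 20 and an exact 95% Clopper-Pearson interval excluding equality. This rule compares 2 libraries and has no replicate check. The biological coefficient of variation came from the common dispersion of edgeR on genes with at least 10 counts in both. The median ratio of a list was placed among 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used.

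The rules were tested on simulated data. In 20 simulations with counting error alone, the between-heart rule called a mean of 10.5 genes and at most 17. Of genes simulated at a true fold of 4, 100% were called, and of those at 0.4, 98%. Alternatives covered the second quantification, rescaled, posterior mean and length-free abundances, other scalings including DESeq2 1.42.0 size factors and the spike-ins, other filters and each library alone. A comparison of alleles of the parental strains was not analysed here. Single values of a few genes in the fixed lists, pairs and isoform genes are not reported here.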

Results

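Total RNA from the hearts of 2 female mice at 4 days of age, offspring of a cross of C57BL/6J and CAST/EiJ as the strain label B6CASTF1/J gives it, was profiled to describe gene expression in the neonatal heart. Nuclear protein-coding genes took 71.1% ± 0.0918 of the expected counts (SD, n = 2) and mitochondrial ribosomal RNA took 11.5% ± 0.453. Mitochondrial messenger RNA made up 5.89% ± 0.0245, long noncoding RNA 4.71% ± 0.0136, small structural RNA 3.53% ± 0.236 and pseudogenes 2.49% ± 0.0994. The libraries held 36175363 and 32509660 expected counts in replicates 1 and 2. Of these, Gm26917 alone held 1056340 and 914838, so the long noncoding share rests largely on a single gene. Its class is that of the annotation, and whether its reads come from another kind of RNA was not tested. A TPM of at least 1 was reached by 13750 and 13953 genes, of which 12093 and 12160 were protein-coding. By TPM, nuclear protein-coding genes held 45.6% ± 0.0181, because short structural RNAs weigh more on that scale.

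The genes with the highest TPM were the signal recognition particle RNAs Rn7s1 and Rn7s2, at 84224 ± 7358 each. Their values were identical in each library, so reads were split between these copies and the single values are uncertain. Next came the mitochondrial ribosomal RNAs mt-Rnr2 (77055 ± 4016) and mt-Rnr1 (42125 ± 3341), the small nuclear RNA Rn7sk (30587 ± 1963) and the cytochrome oxidase transcript mt-Co1 (21015 ± 328). Gm28661, an unprocessed pseudogene, stood at 17472 ± 193 and the noncoding Gm26917 at 14333 ± 217, ahead of mt-Nd1 (9340 ± 140) and mt-Atp6 (8565 ± 137). Gm28661 (chromosome 1, 24614885 to 24615565) and mt-Atp6 (chromosome M, 7927 to 8607) have spans of equal length. Whether reads were shared between Gm28661 and mt-Atp6 was not tested, so their order and the shares of their classes are uncertain. Of the structural small RNA list, 12 of 14 members reached a TPM of 1, Rpph1 stood at 5894 ± 421 and Rmrp at 2800 ± 226, while Rny3 and Gm24187 were listed at 0 in both libraries. In the second quantification Rn7s1, Rn7s2 and Rn7sk fell to TPM values under 1, so the level of short RNAs depended on the quantification. Among the nuclear noncoding list, Malat1 reached 3268 ± 365, Xist 85.4 ± 4.60 and Meg3 57.0 ± 1.41, and 11 of 15 members had a TPM of at least 1.

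Xist, the RNA that coats the inactive X chromosome (mm10 chromosome X, 103460366 to 103483254, minus strand), had 34307 counts in replicate 1 and 32882 in replicate 2. Its partners were lower, with Jpx at 6.17 ± 0.601 TPM, Ftx at 2.38 ± 0.474 and Tsix at 1.06 ± 0.354. Genes known to escape X inactivation were expressed in both hearts, from Ddx3x (118 ± 2.98), Eif2s3x (86.8 ± 5.69), Kdm5c (32.1 ± 1.26) and Kdm6a (23.2 ± 0.552) to Utp14a (9.60 ± 0.679) and Pbdc1 (8.71 ± 0.205). The 8 Y-linked genes summed to 4 counts in replicate 1 and 3 in replicate 2. Ddx3y had 1 and 0 counts, Eif2s3y 1 and 1, Kdm5d 0 and 1, and Uty 2 and 1, while Sry, Zfy1, Zfy2 and Usp9y were at 0 in both. In the second quantification the same 8 genes summed to 222 counts over both libraries, an alternative added after the data were seen.

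Spike-ins took 0.582% of counts in replicate 1 (exact 95% binomial interval 0.580 to 0.585) and 0.547% in replicate 2 (0.545 to 0.550). Across the 63 spike-ins with a TPM above 0 in both, Pearson r of log10 TPM was 0.992, and spike-ins are not independent replicates. Across 55536 genes, which are not independent replicates either, Pearson r of log2(TPM + 1) between the hearts was 0.995 and Spearman rho 0.932. The between-heart biological coefficient of variation was 9.02% over 16473 genes.

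Contractile genes were among the highest nuclear messenger RNAs. Across the fixed lists, 35 of 44 were expressed, meaning that no fewer members had a TPM of at least 1 in both hearts than did not. All 27 sarcomere list members had a TPM of at least 1 and 25 lay in the top 10% of expressed genes, with a sum of 46411 ± 280 TPM (4.64% ± 0.0280 of the total). Such shares depend on the quantification: the share of total, sarcomere, was 7.15% in the second and 8.36% by CPM, and 42 of the 44 list shares differed in the second by more than 1 SD of the libraries. Myl2, the ventricular regulatory light chain (chromosome 5, 122100951 to 122113472), led at 8324 ± 178, followed by cardiac actin Actc1 (chromosome 2, 114047282 to 114053548) at 7516 ± 367, alpha myosin heavy chain Myh6 (chromosome 14, 54941921 to 54966927) at 6949 ± 126 and Myl3 at 3906 ± 303. The ventricular list summed to 14192 ± 474 TPM with 13 of 14 members at a TPM of at least 1, and the atrial list to 2509 ± 264 with 16 of 17, led by the natriuretic peptide Nppa (792 ± 104), Myl7 (656 ± 85.0), Myl4 (396 ± 38.0) and Pam (386 ± 10.4).

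All 18 calcium-handling genes were expressed, with the calcium pump Atp2a2 at 2242 ± 21.5 TPM, its inhibitor Pln at 1423 ± 65.0, the exchanger Slc8a1 at 449 ± 5.16 and the store protein Casq2 at 396 ± 12.4. Channels and junctions had 19 of 22 members at a TPM of at least 1, including the gap junction gene Gja1 (324 ± 11.6), the potassium channel subunit Kcne1 (135 ± 7.83) and Abcc9 (80.7 ± 1.46). The conduction system list was low, with 10 of 14 members and a sum of 159 ± 27.7, led by Igfbp5 (84.0 ± 28.8) and Cacna1g (23.3 ± 2.38). Of 25 cardiac transcription factors 22 were expressed, among them Hopx (197 ± 7.38), Mef2a (110 ± 1.24) and Gata4 (104 ± 4.40).

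Metabolic genes were expressed throughout. All 25 genes of fatty acid oxidation, 20 of the citric acid cycle, 34 nuclear genes of oxidative phosphorylation and 21 of glycolysis had a TPM of at least 1 in both hearts. Their sums were 8634 ± 164, 6351 ± 86.4, 20746 ± 639 and 6961 ± 40.1 TPM. Leading members were Fabp3, a fatty acid carrier (2780 ± 46.7), Acaa2 (624 ± 32.7), Idh2 (761 ± 47.7), Mdh2 (628 ± 18.6), Atp5b (2884 ± 56.0), Cox6b1 (1384 ± 150), Gapdh (1601 and 1584 in replicates 1 and 2) and Aldoa (1018 ± 22.5). The 13 mitochondrial messenger RNAs summed to 79005 ± 1390. Ribosomal protein genes summed to 10014 ± 85.0 with all 28 expressed, Rplp1 being the highest at 852 ± 0.926. Of the thyroid hormone response list 12 of 13 genes were expressed, including Thra at 79.1 ± 4.74 and Klf9 at 13.4 ± 1.80, and Dio3 was at 0 in both libraries. Hypoxia-linked genes had 14 of 15 members expressed, with Vegfa at 92.5 ± 10.2 and Pdk1 at 61.2 ± 5.48.

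Fixed pairs of related genes set isoforms typical of different stages or muscles against each other. Of 29 pairs evaluated, the second gene was higher in 18, the first in 7, and 4 were not called. Adult cardiac myosin Myh6 exceeded the fetal Myh7 (774 ± 10.8 TPM) with a log2 ratio Myh7/Myh6 of -3.17 ± 0.01 (SD, n = 2), 8.98-fold, and of -2.09 in the second quantification. Cardiac troponin I Tnni3 (2147 ± 94.4) exceeded the slow form Tnni1 (904 ± 11.5) 2.37-fold, with a log2 ratio of -1.25 ± 0.05. The log2 ratio Tnni1/Tnni3 was smaller in size in the second quantification (-0.86) and by CPM (-0.49). Tnnt2 (3101 ± 195) exceeded Tnnt1 (20.4 ± 1.68) 152-fold, Tpm1 (3240 ± 26.0) exceeded Tpm2 (53.7 ± 9.38) 60.9-fold, and Actc1 exceeded the skeletal actin Acta1 (263 and 125 in replicates 1 and 2) 41.4-fold. The last ratio differed between the hearts, at -4.89 and -5.86 on the log2 scale. Myl3 exceeded Myl4 by 9.86-fold and Myl2 exceeded Myl7 by 12.7-fold (log2 ratio Myl7/Myl2 -3.67, and -4.33 in the second quantification).

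**Figure D1:**
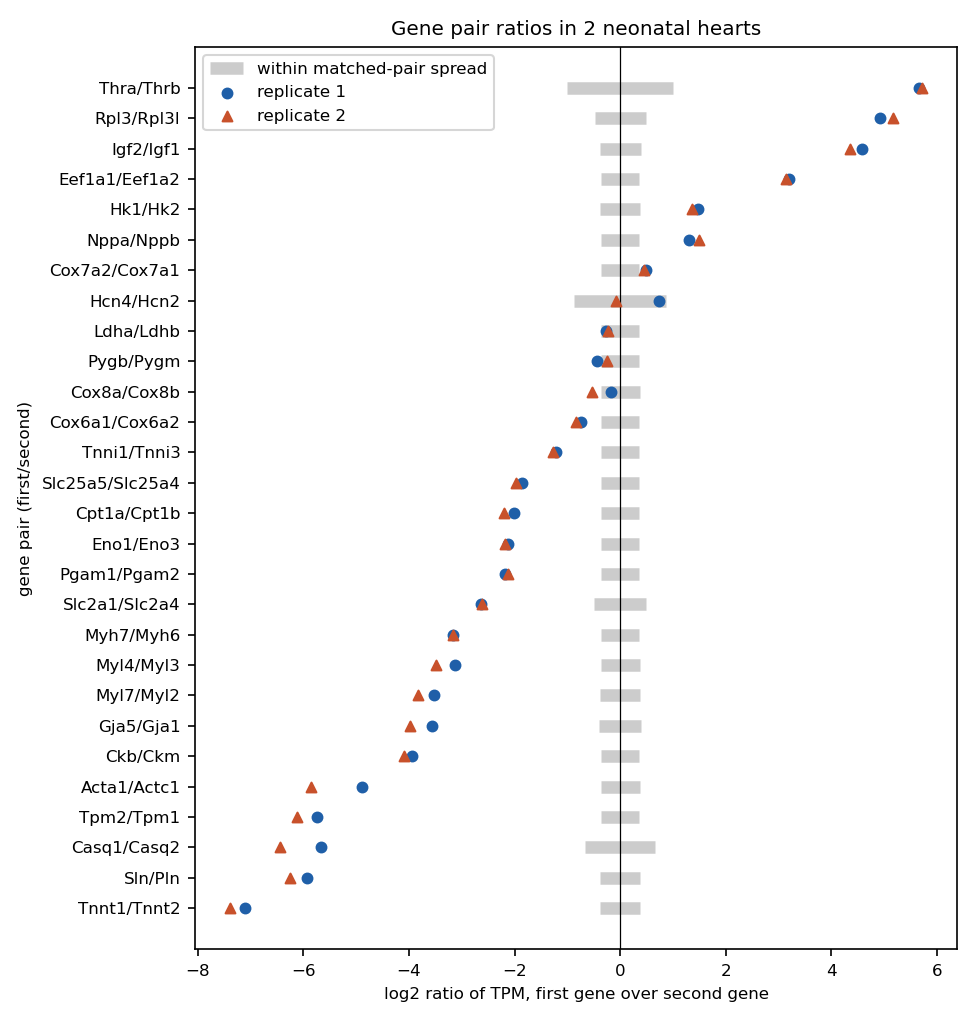
Log2 ratio of TPM of the first over the second gene of 28 of the pairs evaluated (horizontal axis), with circles for replicate 1 and triangles for replicate 2, and grey bars for the spread of matched random pairs. Ratios run from -7.25 for Tnnt1/Tnnt2 to 5.70 for Thra/Thrb as means of both hearts.

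In energy metabolism, Ckm (1235 ± 2.10) exceeded Ckb (76.4 ± 5.18) 16.2-fold, the insulin-responsive glucose transporter Slc2a4 (45.9 ± 1.51) exceeded Slc2a1 (7.42 ± 0.325) 6.19-fold, and Cpt1b (263 ± 4.68) exceeded Cpt1a (61.2 ± 4.19) 4.30-fold. Eno3 (583 ± 14.0) exceeded Eno1 (131 ± 6.55) 4.45-fold, Pgam2 (318 ± 13.6) exceeded Pgam1 (71.1 ± 1.13) 4.47-fold (log2 ratio Pgam1/Pgam2 -2.16, and -1.004 by CPM) and Slc25a4 (1394 ± 27.0) exceeded Slc25a5 (370 ± 10.4) 3.77-fold. The log2 ratio Slc25a5/Slc25a4 was -1.92, and -2.55 by CPM. Hexokinase Hk1 (104 ± 4.32) was 2.68-fold above Hk2 (38.9 ± 0.643). Among cytochrome oxidase subunits Cox6a2 (485 ± 36.6) exceeded Cox6a1 (281 ± 9.91) 1.72-fold, a call lost in the second quantification, while Cox7a2 (428 ± 1.79) was 1.39-fold above Cox7a1 (309 ± 2.44), a call lost at the 99th percentile. The log2 ratio Cox7a2/Cox7a1, 0.47 in the first quantification, was 1.52 in the second and 1.25 by CPM. Not called were Ldha (507 ± 5.08) against Ldhb (603 ± 2.97), Pygb (158 ± 8.29) against Pygm (207 and 194 in replicates 1 and 2), Cox8a (387 ± 27.7) against Cox8b (493 ± 49.1) and Hcn4 (4.92 ± 0.905) against Hcn2 (3.93 ± 0.806). Ldha against Ldhb was called in the second quantification (log2 ratio Ldha/Ldhb -1.01), Hcn4 against Hcn2 by CPM (log2 ratio Hcn4/Hcn2 1.29), Cox8a against Cox8b in replicate 2 alone (-0.52) and Pygb against Pygm in replicate 1 alone (-0.44).

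Pln exceeded Sln (20.9 ± 2.37) 68.4-fold, Casq2 exceeded Casq1 (6.24 ± 2.52) 66.3-fold and Gja1 exceeded Gja5 (24.0 ± 4.00) 13.6-fold. The elongation factor Eef1a1 (2015 ± 32.3) was 8.97-fold above Eef1a2 (225 ± 3.22), Rpl3 (265 ± 4.41) 33.0-fold above Rpl3l (8.06 ± 0.849) and Thra 51.8-fold above Thrb (1.52 ± 0.0495). By CPM the log2 ratio Thra/Thrb was 5.08, against 5.70 by TPM. The growth factor Igf2 (768 ± 109) exceeded Igf1 (34.4 ± 1.11) 22.2-fold (log2 ratio Igf2/Igf1 4.47, and 2.98 by CPM) and Nppa exceeded Nppb (302 ± 66.6) 2.64-fold. Dio2 stood at 1.47 ± 0.120 TPM, and with Dio3 at 0 that pair was not evaluated.

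Proliferation genes were expressed in both hearts. All 26 genes of the G2 and mitosis list and all 22 of the S phase list had a TPM of at least 1, with sums of 921 ± 89.1 and 640 ± 71.4. They were led by Top2a (91.3 ± 9.64), Prc1 (68.6 ± 8.81), Pcna (87.7 ± 9.84) and Rrm2 (86.9 ± 13.5). Of the cell cycle regulators 16 of 18 were expressed, among them Cdk4 (140 ± 1.70) and Ccnd2 (128 ± 4.59). Replication-dependent histone genes summed to 3517 ± 472 with 22 of 22 expressed, Hist1h4h at 606 ± 88.4 and Hist2h3b at 451 ± 72.3. Imprinted genes had 30 of 34 members expressed, including Gnas (825 ± 41.5), Igf2, H19 (588 ± 114) and Mest (270 ± 19.9), and Phlda2 was at 0 in both. Of the stress list 18 of 18 genes were expressed, led by Hspa8 (532 ± 8.12) and Hspb1 (172 ± 5.01), and of the immediate early list 18 of 22, led by Jund (116 ± 4.89).

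Markers of the other cardiac cells were present. All 29 extracellular matrix genes (sum 5486 ± 448), 15 fibroblast genes (2826 ± 313), 16 endothelial genes (1372 ± 45.0), 14 smooth muscle and pericyte genes (1269 ± 35.7) and 8 lymphatic endothelial genes (57.3 ± 0.735) had a TPM of at least 1. Col3a1 stood at 716 ± 107, Sparc at 641 ± 26.0, Vim at 631 ± 26.3, Fabp4 at 388 ± 28.5, Cav1 at 222 ± 11.1, Acta2 at 508 ± 60.6 and Prox1 at 25.1 ± 0.608. The endocardial list (7 of 8, sum 105 ± 14.1), the epicardial and mesothelial list (11 of 12, 94.2 ± 16.8) and the macrophage and myeloid list (14 of 18, 67.2 and 94.2 in replicates 1 and 2) were lower, with Cgnl1 at 25.8 ± 0.962, Aldh1a2 at 25.7 ± 0.771 and Lyz2 at 15.0 ± 6.51.

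Markers of tissues outside the heart were mostly low. Expressed members numbered 1 of 14 in the lymphocyte list (sum 6.37 ± 2.36 TPM), 3 of 15 in the thymus list (24.1 ± 4.01), 2 of 12 in the liver list (13.9 ± 2.33) and 5 of 15 in the neural and Schwann list (74.2 ± 16.6). The lung and airway list had 1 of 12, Hopx, which the heart also expresses. The adipocyte list had 6 of 13 (469 ± 23.0) and the skeletal muscle list 7 of 18 (1481 ± 137), whose leading members Fabp4 and Ckm are also cardiac or endothelial genes. The erythroid list summed to 8822 ± 12076, an SD larger than the mean, while the embryonic globin list summed to 0.280 ± 0.396.

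The hearts differed most in transcripts of red blood cells. All 9 tested erythroid genes were lower in replicate 2 and 7 were called, with a list median log2 ratio of -6.27, which is 77.1-fold. Adult globins Hbb-bs (chromosome 7, 103826534 to 103828096) fell from 84791 counts in replicate 1 to 894 in replicate 2, and Hba-a1 (chromosome 11, 32283511 to 32284465) from 89126 to 988. Alas2, the erythroid enzyme of heme synthesis, had 4322 and 49 counts, a log2 ratio of -6.34 (exact 95% interval -6.79 to -5.95). Hba-a2 had a ratio of -6.29 and Hbb-bt of -6.27. Globins made up 0.698% of all counts in replicate 1 and 0.00865% in replicate 2.

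Skeletal muscle transcripts and the myelin gene Mbp were also higher in replicate 1. All 9 tested skeletal muscle genes were lower in replicate 2 by scaled counts, 8 were called, and the list median was -2.51. The member not called, Ckm, was nearly level by TPM, at 1234 and 1237 in replicates 1 and 2. Chosen after their values were seen, the neonatal myosin Myh8 had 1301 and 178 counts, Mylpf 185 and 12, Atp2a1 330 and 16, and Tnnc2 81 and 1 (log2 ratio -5.65, interval -11.55 to -3.71). Mbp, also chosen after its value was seen, had 587 and 209 counts, a ratio of -1.38. The neural and Schwann list had a median of -0.33, with 4 of 6 members lower. The epicardial and mesothelial list had a median of -0.63 with 12 of 12 members lower, of which Krt19 was called at -1.02. The atrial list had a median of -0.33 (16 of 16 lower), the endocardial list -0.38 (7 of 7) and the liver list -0.54 (2 of 3), and no member of these was called.

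In total 73 genes (62.4% of those called) were called higher in replicate 1 and 44 higher in replicate 2 among 13598 tested. With spike-in scaling, which moved the median gene by 0.13 on the log2 scale, 60 were higher in replicate 1 (46.9%) and 68 in replicate 2. Both quantifications called 45 of the 73 and 11 of the 44, a count added after the data were seen. Pseudogenes and numbered gene models made up 28 of the 73 and 27 of the 44, and 1 and 5 of those called by both quantifications. Among the 10 largest ratios upward in replicate 2 were Prn, Gm12070, Gm6565, Rpl15-ps3, Pgk1-rs7, Gm49037, Gm14288, Gm28052, Gm2260 and a second gene of the symbol Chtf8, of which the second quantification called the last 2. Prn had 0 and 196 counts and Gm12070 0 and 148. Downward, Gm45837 (374 and 0 counts), Gm14440, Gm2274, Gm10132 and Gm4294 stood beside Alas2 and the globins, and of these gene models the second quantification called Gm2274. Apart from Alas2 and the globins, the ratios of the genes named here are uncertain, with posterior SDs from 25.9% (Gm2274) to 258% (Pgk1-rs7) of the count. Their reads can be shared with copies or with other genes, and which was not tested.

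Several lists moved by smaller amounts. Of 40 lists placed, 13 lay below and 7 above the central 95% of random lists, where 2 would if genes varied independently. Genes of a list can vary together between 2 animals, so more than 2 lists can lie outside without a special cause. Macrophage and myeloid genes were higher in replicate 2 at a median of 0.37 (15 of 15 members), as were replication-dependent histones at 0.18 (19 of 22), fibroblast genes at 0.16 (14 of 15), S phase genes at 0.15 (21 of 22) and G2 and mitosis genes at 0.10 (26 of 26). Smooth muscle and pericyte genes had a median of 0.07, which no longer lay above the range at a mean TPM of at least 5, and extracellular matrix genes had a median of 0.02. Immediate early genes were lower in replicate 2 at -0.17 (15 of 18, Fos called at -1.11), and imprinted genes at -0.15 (28 of 31). Glycolysis (-0.10), structural small RNA (-0.10), conduction system (-0.11) and adipocyte (-0.12) medians were below the range, and turned positive with spike-in scaling, which adds the same 0.13 to every gene and leaves the place of a list among random lists unchanged. The conduction system and adipocyte lists were near the edge of the range (percentiles 2.18 and 2.00), and neither lay below it at a mean TPM of at least 5. Sarcomere (-0.07), calcium-handling (-0.06), ion channel and junction (-0.03), cardiac transcription factor (-0.01), ventricular (0.00), oxidative phosphorylation (-0.03) and ribosomal protein (-0.07) medians lay inside it.

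**Figure D2:**
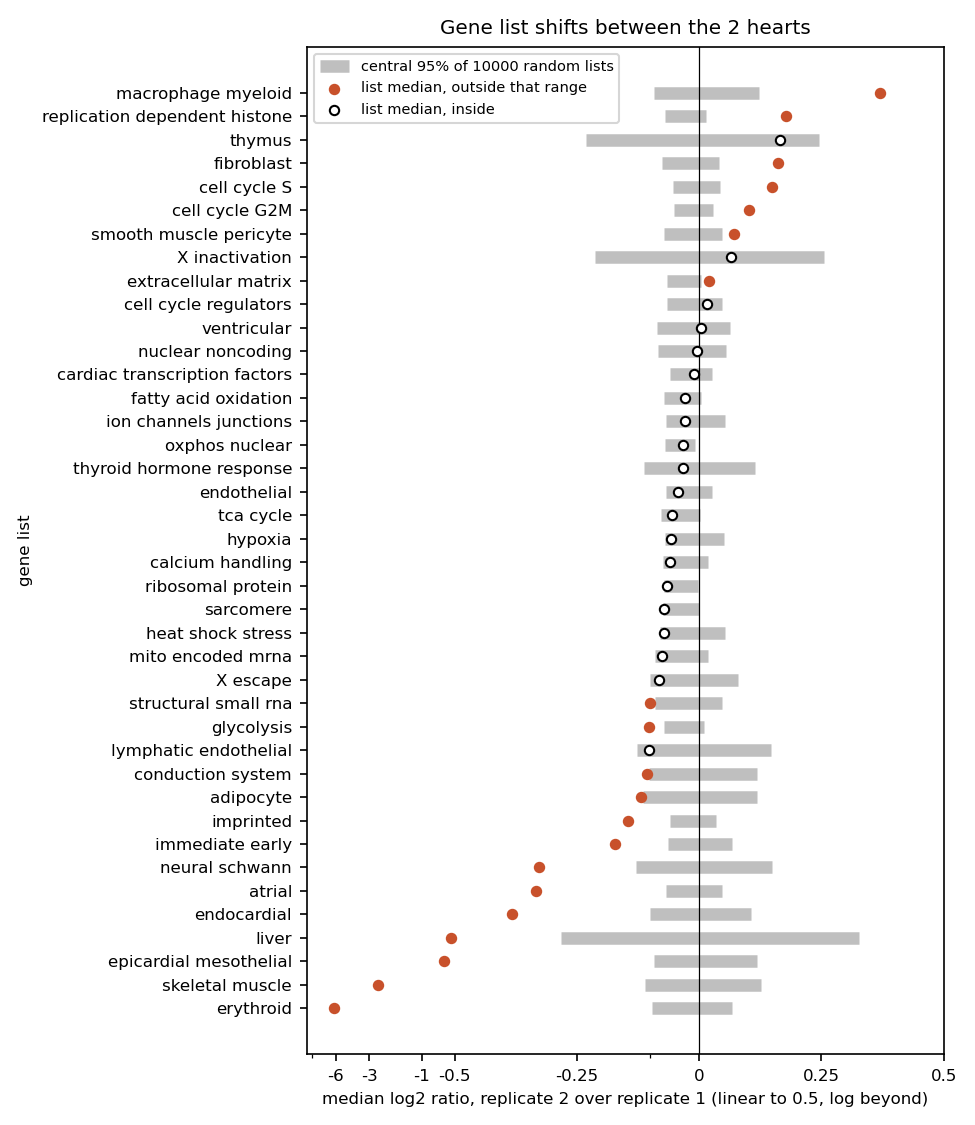
Median log2 ratio of replicate 2 over replicate 1 for 40 gene lists (horizontal axis, linear to 0.5 and logarithmic beyond), with grey bars for the central 95% of 10000 random lists. The erythroid list at -6.27 and the skeletal muscle list at -2.51 lie farthest from the bars, and glycolysis, structural small RNA, conduction system and adipocyte medians turn positive with spike-in scaling, which moves all genes alike by 0.13.

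Transcript shares were compared for 25 genes in both quantifications. In the first, 23 genes had the same dominant transcript in both hearts, Tpm2 being among the exceptions, and in the second 24 did, the exception being Pdlim5. Both quantifications gave the same dominant transcript for 16 genes. Tpm1-205 held 93.3% ± 0.541 of Tpm1 in the first and 68.5% ± 0.878 in the second, Pdlim3-201 80.6% ± 1.14 and 82.4% ± 2.64, Ryr2-201 65.1% ± 3.50 and 63.7% ± 4.14, and Ttn-201 36.0% ± 0.146 and 34.7% ± 0.597. Myh6-201 held 36.4% ± 2.25 and 61.4% ± 0.838, Mef2d-201 60.8% ± 1.45 and 56.4% ± 1.25, and Pkm-201 48.6% ± 0.669 and 48.6% ± 2.04. Shares from 50.6% to 60.0% in the first quantification belonged to Ldb3, Myom1, Bin1 and Actn4, and shares from 27.0% to 48.8% to Camk2d, Fhl1, Cacna1c, Fn1 and Rbfox2. The dominant transcript differed for Tnnt2, where Tnnt2-207 led the first at 43.4% ± 2.92 and Tnnt2-209 the second at 61.7% ± 0.233, and likewise for Tnni3, Mef2c, Nebl and Slc8a1, among others.

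Counts of short genes were lower in the second quantification than in the first. Over protein-coding genes with at least 100 counts, the median count ratio of second over first was 0.622 ± 0.00465 for 96 genes under 500 nt, 0.888 ± 0.00769 for 226 genes from 500 to 700 nt, and 1.09 ± 0.00463 for 4240 genes of 3000 nt or more. Spike-ins had the same trend at lower ratios than genes, with a median of 0.496 for 7 under 700 nt and 0.779 for 14 of 1000 nt or more.

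**Figure D3:**
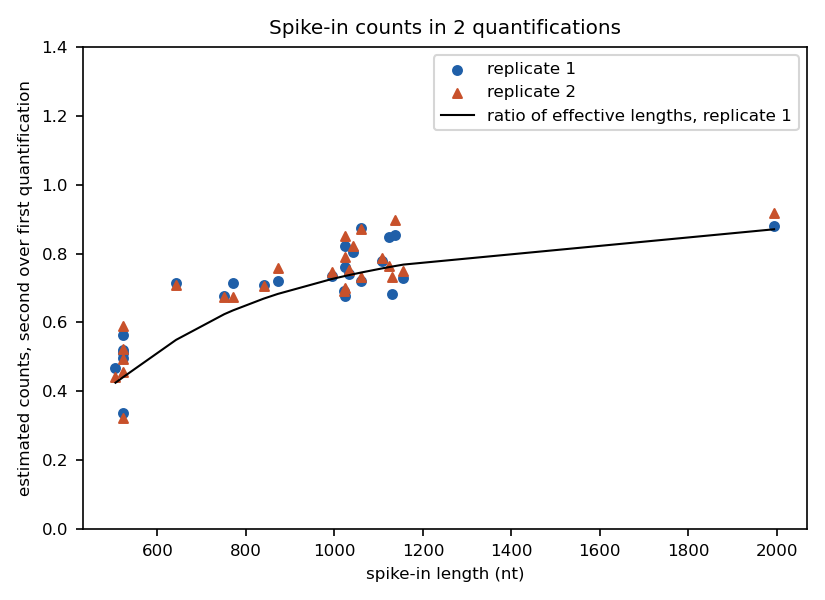
Ratio of estimated counts in the second over the first quantification (vertical axis) against length in nt for 26 spike-ins with at least 100 counts, with circles for replicate 1, triangles for replicate 2 and a line for the ratio of effective lengths. The median ratio was 0.496 under 700 nt and 0.779 from 1000 nt.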

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

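The tests of explanations in this part were chosen only after the results were seen, while the medians of the fixed lists and their alternatives were planned. Features identified by a number only, which no comparison used, had 6 expected counts in replicate 2 and 0 in replicate 1. These are sums over 26248 features, and nothing was drawn from them.

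Erythroid transcripts were 77.1-fold lower in replicate 2 as a list median. Depletion of globin transcripts from that library alone would leave other erythroid genes in place, but the 7 measured members that are not globins had a median log2 ratio of -2.97, below the range of random lists (-0.15 to 0.15). Reads shared among globin copies are argued against too, since the weakest ratio of the 7 called members in the second quantification was -3.11. Whether whole blood with its white cells was the source cannot be told apart from red cells alone: neutrophil transcripts had a median of 0.37, and the white cell share of such blood is not in the data. A difference in retained red cells may underlie the pattern as a hypothesis, and no biological explanation was tested because the design has a single group.

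Skeletal muscle transcripts were higher in replicate 1, at a list median of -2.51. Reads shared with cardiac paralogs would be lost or turn in the second quantification, where the weakest of the 8 called members still had -1.15, and the largest posterior SD among them was 0.264% of the count. Tissue next to the heart carried into replicate 1 is a candidate explanation: the Schwann, mesothelial and adipocyte lists, 3 of 3, lay below the range of random lists as well. These lists were picked after their shifts were seen, so that count is no test. Lists of the heart itself were also below the range, atrial at -0.33 (16 of 16 lower) and endocardial at -0.38 (7 of 7). The thymus list went the other way, at 0.16 (3 of 3 higher in replicate 2), inside the range. The adipocyte list, at -0.12 with 4 of 8 members lower, lay below the range in 5 of 7 alternatives and had a median of 0.00642 at a mean TPM of at least 5 (median log2 ratio between hearts, adipocyte), although Adipoq (81 and 16 counts) and Plin1 (198 and 51), picked after their values were seen, were called in both quantifications. The heart also expresses Ckm and Acta1 of the skeletal list, so the amount carried over was not estimated, and no biological explanation was tested.

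Short targets had lower counts in the second quantification. A loss of reads independent of length is argued against by spike-ins, whose ratio under 700 nt was 0.636 of that from 1000 nt (bootstrap 95% interval 0.563 to 0.775). Reads dropped near target ends according to the fragment length could produce such a trend, and spike-in medians of 0.496 under 700 nt and 0.779 from 1000 nt stood beside 0.444 and 0.747 from the effective lengths. This stays open, because the median log2 distance to the effective length ratio (0.109) was not below that to a constant ratio (0.116) by more than its spread (bootstrap interval of the difference -0.15 to 0.05). The comparison can decide little, since a constant ratio is itself argued against above. Genes had higher ratios than these spike-ins, at 0.971 from 700 to 1000 nt and 1.01 from 1000 to 1500 nt. No effective length prediction was made for genes. No biological explanation was tested.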

How the results depend on the processing

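The alternatives were planned, except for the calls made by both quantifications and the second quantification of Y-linked genes, which were added after the data were seen. Under the alternatives 35 to 37 of 44 lists were expressed, 18 to 19 pairs had the second gene higher and 6 to 8 the first, and 16 to 23 lists lay outside the random range. Genes higher in replicate 1 and in replicate 2 numbered 208 and 149 with no filter on TPM, 25 and 11 at a mean TPM of at least 5, 177 and 134 at 1.5-fold, and 45 and 11 by both quantifications. With spike-in scaling 60 were higher in replicate 1 and 68 in replicate 2. That scaling adds the same 0.13 to every log2 ratio, which moves genes across the fixed 2-fold line. Why the spike-ins and TMM gave different scales was not tested. The coefficient of variation was 8.21% at 100 counts in both and 9.69% without a filter. Pearson r was 0.988 with a pseudocount of 0.1 and 0.991 for genes with a TPM of at least 1. Protein-coding genes took 45.6% of TPM, the spike-in share was 0.684% of counts outside mitochondrial genes, and Y-linked genes 222 counts in the second quantification.

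Some list medians changed sign. Spike-in scaling adds the same 0.13 to every gene and leaves the place of a list among random lists unchanged, so its sign changes follow from the scaling itself. With it the median log2 ratio between hearts, glycolysis, was 0.0319, the median log2 ratio between hearts, adipocyte, 0.0145, and that of the conduction system 0.0280. The median log2 ratio between hearts, structural_small_rna, was 0.0336, and the adipocyte value at a mean TPM of at least 5 was 0.00642. In the second quantification Gm12070 (-0.43) reversed, as did Gm14440 (0.10) and Gm10132 (0.10), whose values there reflect scaling alone because almost no counts were assigned to them in either library. Of the 20 genes named by their ratio between the hearts, 8 were also called there and 12 were not. Leaving out a library gave 35 to 37 expressed lists and 19 and 7 called pairs; between-heart results need both libraries, and a dominant transcript is trivially constant in 1. No paired analysis was possible because there is a single group.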

Other observations

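The tests of the neutrophil, platelet and interferon lists in this part were chosen only after the results were seen. Neutrophil genes were slightly higher in replicate 2, with a median log2 ratio of 0.37 over 5 members, all higher after scaling, including S100a8 (50 and 60 counts), Ltf (53 and 82) and S100a9 (75 and 70). Only Ltf had an exact 95% interval excluding equality (0.22 to 1.27). Those of S100a8 (-0.19 to 0.94), S100a9 (-0.48 to 0.50), Ngp and Lcn2 included it. Platelet genes had a median of -0.46 over 4 members, below the range of random lists (-0.39 to 0.39), with 2 members lower and 2 higher. Itga2b had 88 and 33 counts and Ppbp 36 and 16, each with an interval excluding equality. Pf4 had 126 and 126, so its ratio of 0.11 reflects scaling alone. Gp1bb had 7.64 and 20.5, a ratio of 1.45 (interval 0.27 to 2.89) that was 0.10 in the second quantification. Rsad2, an interferon-induced gene, had 375 and 44 counts (log2 ratio -2.97, exact 95% interval -3.47 to -2.53), while the interferon response list that includes it had a median of 0.00 over 9 members, with Ifi35 at 196 and 181 counts.

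Chosen after their values were seen, further genes higher in replicate 1 in both quantifications included Tent5c (3552 and 187 counts), Slc25a37 (2303 and 528), the red cell enzyme Bpgm (1616 and 556), the membrane skeleton gene Epb41 (5920 and 2452) and Ube2l6 (907 and 174). Genes higher in replicate 2 in both quantifications included Lyz1 (25.5 and 49.3 counts), Aif1 (15 and 30), Pglyrp1 (8 and 25) and Krt10 (63 and 153).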
